A study of Homo sapiens with 52 samples.

How the data were processed

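RNA of human embryonic stem cells was measured on Affymetrix arrays of 2 designs, the A chip and the B chip of the HG-U133 set, which carry different probe sets. The line H1 was sampled before treatment (day 0) and on days 1 to 10 of differentiation in 5 µM retinoic acid. Undifferentiated H9 and HUES8 cells, kept in mTeSR medium on Matrigel like the untreated H1 cells, were sampled once each. Per the labels, every group had 2 biological replicates, so 13 groups gave 26 samples and 52 arrays. Total RNA was converted to biotinylated cRNA. Both deposited copies of the values were read, and they differed by at most 5.0e-06 of a value.

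The deposited signal is an intensity on a linear scale, made by the authors with MAS5 according to the submitters' processing notes, which give no version. The 2% trimmed mean of every array was 499.9 on the A chip and 500.0 on the B chip, so the arrays had been scaled to a common mean. Beside each signal the deposited table gives a detection p-value, from which calls were computed: present under 0.05, absent from 0.065 and marginal between. The 52 columns of calls in that table were not used here. No transformation beyond log2 was applied to the signal in the reported values.

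Probe sets were assigned to genes by the array annotation: 34491 named 1 gene, 1597 named several genes and 8704 named none, and only the first kind was used. Of these, 34454 were matched by gene identifier to the human reference annotation, which was used for names alone. Genome positions are not given, because the arrays were not tied to a genome build here. To protect identity, 52 probe sets of sex-linked genes were left out of every count. A probe set had to be called present on at least 2 of the 26 arrays of its chip, which 21500 probe sets did. For each gene the probe set with the highest mean log2 signal was used, with those whose names mark cross-hybridisation taken last. This gave 12183 genes, 6803 from the A chip and 5380 from the B chip. POU5F1, TDGF1 and TNNT2 had no probe set annotated to them alone, and SOX1 and CGA were not called present on 2 arrays, so these 5 genes were not analysed here.

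A linear model with 1 mean per group was fitted to each chip with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. It had 13 residual degrees of freedom, and prior degrees of freedom of 6.80 on the A chip and 8.15 on the B chip. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes of both chips, separately for each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were an F test over the 11 H1 days, each day against day 0, each day against the day before, H9 and HUES8 against H1 day 0, and HUES8 against H9. For day 10 against each of 3 undifferentiated lines, and for genes that rose by day 3 and fell by day 10 or the reverse, the largest p of the tests involved was taken and adjusted. With 2 replicates per group the number of arrays limits the precision, and the tests borrow the spread of all 13 groups.

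Changes are differences of group means on the log2 scale. Where a gene was called absent or marginal on both arrays of the lower group and present on at least 1 of the higher group, its change is given as "at least N-fold". For this fold, a lower-group signal below the lowest signal called present on its array was raised to that signal. That level is shared by all probe sets of an array and is not the detection limit of the gene. Where the signals already lay above it, as for AMOTL1 and FAT3, the fold equals the fitted change. It carries no sampling error and is not a confidence bound. No fold is given where neither group had a present call.

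The genes named were chosen by rules. These took 19 fixed genes. For day 1 they took the 6 largest rises and falls, and for day 10 the 10 largest, among called genes whose replicates did not overlap and that were present in both groups. They further took up to 6 genes present on both arrays of 1 group and neither of the other, the 5 largest of each transient class, the 4 largest changes per direction between lines, and up to 4 called members of each gene list. Where a list had no called member, up to 2 were taken. Genes named beyond these were chosen after their values were seen. In the paragraphs on lists they were RARA, NRIP1, DLX5, SOX9, AXIN2, TERF1, ID1, LRAT and ALDH1A3. Between lines they were CDKN1A, SESN2, TNFRSF10B, NUSAP1 and TTK, and others are identified where they are named.

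The 26 gene lists were core pluripotency, retinoid metabolism and response, HOX paralogs 1 to 5, HOX paralogs 6 to 13, neural progenitor, neuron, neural crest, surface ectoderm, simple epithelium, trophoblast, definitive endoderm, hepatic and visceral endoderm, primitive streak and early mesoderm, cardiac muscle, smooth muscle with fibroblast and matrix, endothelium, blood, mitosis, DNA replication, p53 targets, BMP targets, WNT targets, cholesterol synthesis, glycolysis, interferon response with MHC class I, and the stress and unfolded protein response. They were tested with limma's camera on the moderated statistics with a preset correlation of 0.01, adjusted over the 26 lists. An estimated correlation, and the fry test, were run beside it. The counts of members called were also made with p adjusted over the list alone. All such counts are of the members measured, so genes not detected or without a probe set of their own are left out. Measured were 7 of 18 trophoblast genes, 8 of 24 HOX paralogs 6 to 13, 7 of 16 surface ectoderm genes and 6 of 16 hepatic and visceral endoderm genes. For primitive streak it was 4 of 12, for cardiac muscle 2 of 15 and for blood 2 of 10. Groups, comparisons, gene rules, lists and most alternatives were fixed before the data were examined.

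The alternatives were quantile normalization, centring on the 100 normalization control probe sets of each chip, no detection filter, a stricter filter of 6 present arrays, a floor at the median signal of absent calls, no intensity trend, the replicate number as a block, the mean of all probe sets of a gene, the series table in place of the matrix, only the H1 arrays, only the arrays of the groups compared, a 2-fold minimum, and leaving out each replicate in turn. A fit with the ACTB 3'/5' signal ratio of each array as a covariate, list tests on the 3 comparisons between lines, the changes along the course of the genes called for H9 against H1, and a test of HOX onset with genes never called placed last, were added after the data were seen. The steps were also tested on simulated data with known changes. At day 10 they recovered 31% of 100 genes changed 2-fold and 72% of 100 genes changed 4-fold, and called 4 unchanged genes. For day 10 against each of 3 lines they recovered 22% and 69%, for the F test 10% and 60%, and for a rise then fall 20% and 60%. The 1 simulated list changed 1.5-fold was called and none of the others was. Simulated genes varied independently, so this does not test false list calls from correlated genes, and the BMP list had an estimated correlation of 0.257. Far fewer genes were changed than the 3116 called at day 10, so recovery in the data may differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.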

Results

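Expression was measured in H1 human embryonic stem cells before and on each of 10 days in 5 µM retinoic acid, a vitamin A derivative used to direct differentiation. Undifferentiated cells of 2 other lines, H9 and HUES8, were measured for comparison. Each of the 13 groups had 2 biological replicates, each read on an A chip and a B chip, 52 arrays in all. The share of probe sets called present ranged from 44.8% to 54.2% on the A chip and from 31.1% to 40.1% on the B chip. Log2 signals of replicates correlated across genes with r from 0.930 to 0.953, genes not being independent replicates. Changes below are log2 differences of group means ± SE with n = 2 per group, tested with limma and adjusted by Benjamini-Hochberg over 12183 genes.

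The number of genes called against day 0 was larger on each later day, though not in every fit. No untreated H1 culture was sampled on days 1 to 10, so effects of retinoic acid and of time in culture were not separated. Of the genes tested, 3300 differed between the H1 days in the F test. Against day 0, 113 genes were higher and 32 lower at day 1, 279 and 183 at day 2, 428 and 224 at day 3, 600 and 349 at day 4, and 773 and 479 at day 5. The counts were 984 and 691 at day 6, 1097 and 784 at day 7, 1169 and 816 at day 8, 1395 and 1105 at day 9, and 1589 and 1527 at day 10. Principal component 1, with 37.9% of the variance, ran from -49.8 and -55.3 in the day 0 samples to 65.5 and 62.96 at day 10. H9 lay at -61.0 and -60.7 and HUES8 at -56.6 and -49.4, beside the untreated H1 cells. Leaving out any 1 replicate of either group gave 244 to 273 genes at day 2, 361 to 401 at day 3 and 1202 to 1314 at day 8. The counts without H1 day 0 replicate 1 or 2 were 570 and 547 at day 4, 747 and 747 at day 5, 1010 and 1094 at day 6, and 1210 and 1190 at day 7. They were 564 without H1 day 4 replicate 1, 800 without H1 day 5 replicate 2, 940 without H1 day 6 replicate 2, and 1240 without H1 day 7 replicate 2. At day 9 they were 1523 without H1 day 0 replicate 2 and 1563 without H1 day 9 replicate 2. After centring on the control probe sets the median change of all genes was -0.20 at day 2, -0.18 at day 3, -0.15 at day 4 and -0.14 at day 5. The splits into higher and lower were then 176 and 245, 259 and 280, 394 and 365, and 481 and 532. From day 6 to day 10 they were 674 and 673, 776 and 787, 914 and 948, 1037 and 1337, and 1544 and 1252. At day 10 quantile normalization gave 1581 and 1750. Which direction held more genes thus turned with the scaling on days 2, 3, 5, 7, 8, 9 and 10. With the replicate number as a block 727 genes were called at day 2. With the ACTB 3'/5' signal ratio as a covariate, added after the data were seen, the counts from day 1 to day 10 were 161, 527, 619, 809, 1285, 1385, 1666, 1428, 1978 and 1716, so growth was not steady after day 7.

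**Figure D1:**
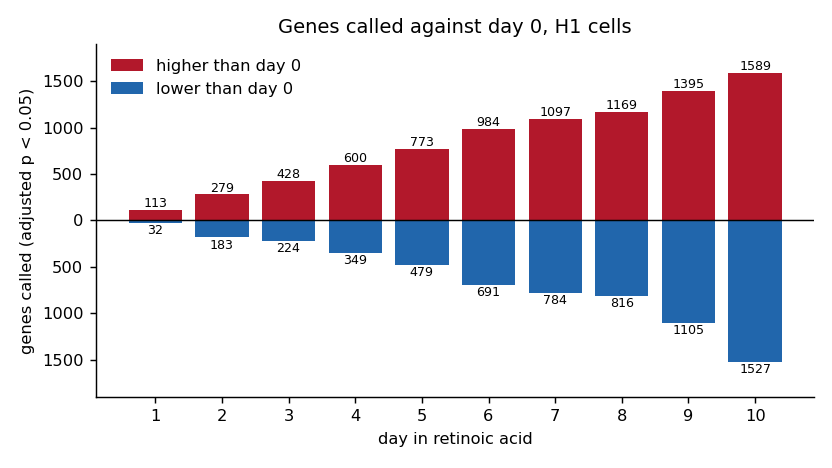
Number of genes called against day 0 (vertical axis, adjusted p under 0.05) on each day in retinoic acid (horizontal axis, days), with genes higher than day 0 above the line and genes lower below it. The counts grow from 113 higher and 32 lower at day 1 to 1589 and 1527 at day 10.

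**Figure D2:**
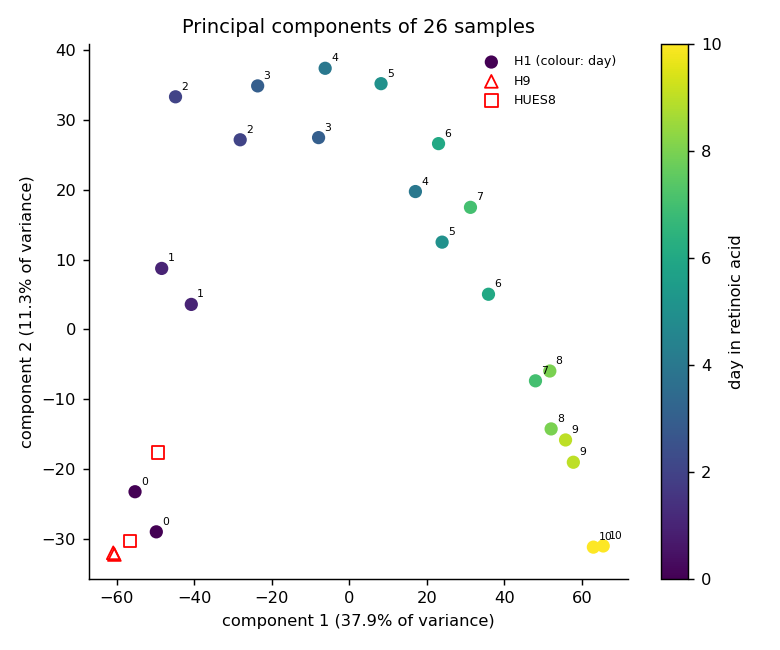
Principal components 1 and 2 of the 26 samples, with 37.9% and 11.3% of the variance, computed on log2 signal of all genes tested. Each point is a sample, with H1 coloured and numbered by day and H9 and HUES8 as open symbols. Day 0 lies at -49.8 and -55.3 on component 1 and day 10 at 65.5 and 62.96.

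Day 1 against day 0 asked what changes first. Genes that sense or degrade retinoic acid were among those that rose. CYP26A1, the cytochrome P450 that degrades retinoic acid, rose by 4.37 ± 0.22 (adjusted p = 2.18e-10). RARB, a retinoic acid receptor and a known direct target, went from absent to at least 22.8-fold higher (adjusted p = 9.23e-07). DHRS3, a retinaldehyde reductase, rose by 1.77 with adjusted p = 0.000894. The other probe sets of RARB gave 2.74 and 0.32. Rises among genes present in both groups were led, after CYP26A1, by DEPTOR, an mTOR inhibitor, with 3.72 ± 0.34. HAS2, a hyaluronan synthase, rose by 3.72 ± 0.56 and ID4, an inhibitor of helix-loop-helix factors, by 3.50 ± 0.32. ARHGAP29 rose by 3.25 ± 0.35 and MYCT1 by 3.16 ± 0.29, and these 5 adjusted p ranged up to 0.000510. By day 10 the changes of DEPTOR and HAS2 were -0.55 and -0.21, with adjusted p of 0.268 and 0.833. Among genes absent on both day 0 arrays, ZNF503, a zinc finger repressor, was at least 107.7-fold higher, and SKAP2, a kinase adaptor, at least 23.2-fold. SMIM10L2A was at least 16.1-fold higher, SMIM43 at least 12.6-fold and TSPYL2 at least 8.72-fold. Falls were led by DUSP6, a phosphatase that acts on ERK, which fell by 2.87 ± 0.62 (adjusted p = 0.0188). HEY1, a Notch target, fell by 2.67 ± 0.44 and SLC39A8, a zinc importer, fell by 2.54 ± 0.35. TOX3 fell by 2.30 ± 0.39, PHLDB2 fell by 2.04 ± 0.36, and POLR3G, an RNA polymerase III subunit abundant in stem cells, fell by 1.93 ± 0.25. With no detection filter a different probe set stood for TOX3 and gave -0.85 (adjusted p = 0.893), and with the mean of its probe sets PHLDB2 had -1.98 (adjusted p = 0.205). Other probe sets gave 2.20 for DEPTOR, -2.66 and -6.01 for DUSP6 and -4.41 for HEY1. With no intensity trend DUSP6 had adjusted p = 0.0653. DUSP6 had adjusted p = 0.112 without H1 day 0 replicate 1, 0.113 without H1 day 0 replicate 2 and 0.173 without H1 day 1 replicate 2. In all, 26 called genes were present on both arrays of 1 day and neither of the other. The count over both directions fell to 88 without H1 day 0 replicate 2, and centring on control probe sets gave 60 higher and 30 lower, with a median change of all genes of -0.14. With only the groups compared 86 genes were called, and with the replicate number as a block 253.

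Of the 26 gene lists, 4 passed at day 1. In the retinoid list 6 of 20 members rose, 7 adjusted over the list alone, and none fell (adjusted p = 9.69e-09, and 0.00774 with an estimated correlation). They included MEIS2, RARA with 1.60, and NRIP1, a receptor corepressor, with 2.46. Among HOX paralogs 1 to 5, which set hindbrain position, HOXB1 and HOXB2 rose from absent, 2 of 10 members, and a second probe set of HOXB1 gave 0.92. Adjusted over the list alone, 4 rose and 1 fell. The list had adjusted p = 0.0193, against 0.233 with an estimated correlation and 0.110 without H1 day 1 replicate 2. In the neural crest list DLX5 and SOX9 rose, 2 of 11, with 4 adjusted over the list alone (adjusted p = 0.00106, and adjusted p = 0.0667 with an estimated correlation). None of the 4 primitive streak genes was called, 1 fell adjusted over the list alone, and the list was lower with adjusted p = 0.0487. With an estimated correlation the adjusted p was 0.192. It was 0.211 without H1 day 0 replicate 1, 0.102 without H1 day 1 replicate 1 and 0.118 without H1 day 1 replicate 2. The other 22 lists had adjusted p of 0.246 or more. Single members of them were called: BMP4, a growth factor absent at day 0, with ID4 and ID1 in the BMP list, AXIN2 among WNT targets, and COL1A1 up, with other probe sets at 0.20 and 0.41, and THY1 down in the matrix list. The BMP list had adjusted p = 0.246 and a median change of -0.09, with 3 rises and 3 falls adjusted over the list alone. In the pluripotency list DNMT3B, a DNA methyltransferase, rose by 1.32 and TERF1 fell by 0.99. Median, mean and test differed in sign for surface ectoderm, simple epithelium, definitive endoderm, hepatic endoderm, glycolysis, stress and BMP lists.

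Day 10 against day 0 compared the end of the course with untreated cells. Most pluripotency genes had fallen, and more genes of the retinoid pathway, the HOX clusters and simple epithelium had risen than had fallen. NANOG, a core pluripotency factor, was at least 58.1-fold lower (adjusted p = 6.53e-09), and SOX2 fell by 3.16 ± 0.34. CYP26B1, a second retinoic acid hydroxylase, was at least 247-fold higher, and COL3A1, a fibrillar collagen, rose 158-fold (7.31 ± 0.60, adjusted p = 2.62e-08), with other probe sets at 6.25, 4.28 and 6.51. GATA6, an endoderm and mesoderm factor, was at least 46.05-fold higher (adjusted p = 1.98e-06). PAX6, an eye and neural factor absent on both day 0 arrays and present on 1 of 2 at day 10, was not called (at least 1.57-fold, adjusted p = 0.569), and its second probe set gave 2.14. AFP, a fetal liver protein, had a change of 0.61 ± 1.09 (adjusted p = 0.737). Other large rises were ERP27, an endoplasmic reticulum protein, with 6.12 ± 0.66, SLC40A1, the iron exporter ferroportin, with 5.95 ± 0.72, and LOC100240734 with 5.80 ± 0.34. IGFBP3, which binds insulin-like growth factors, rose by 5.43 ± 0.27, COL2A1, the cartilage collagen, by 5.34 ± 0.45, and RHOBTB3 by 5.28 ± 0.37. The probe set annotated to MIR99AHG rose by 5.03 ± 1.39, LRP2, an endocytic receptor, by 4.86 ± 0.78, and RAI1 by 4.79 ± 0.46. A second probe set of SLC40A1 gave 1.26, and others gave 1.57 to 5.50 for RHOBTB3, 6.52 for IGFBP3, 8.11 for COL2A1, 2.69 for LRP2, 3.45 for HOXB3 and -5.23 and -3.17 for SOX2. LINC02381 was at least 286-fold higher, MEIS2, a homeobox cofactor, at least 161-fold, HOXB3 at least 134-fold and HOXB2 at least 97.5-fold. ZIC2, a neural zinc finger factor, was at least 204-fold lower.

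Among genes present on day 0 and day 10, the largest fall was that of the probe set annotated to MIR302B, host of a stem cell microRNA cluster, which fell by 7.09 ± 0.52. MACC1-OT1 fell by 6.18 ± 0.55, LINC00458, a long noncoding RNA, fell by 5.96 ± 0.63, and PMAIP1, a proapoptotic BCL2 family member, fell by 5.64 ± 0.34. PTPRZ1 fell by 5.57 ± 0.78, USP44, a deubiquitinase, fell by 5.56 ± 0.34, and THY1, a surface glycoprotein, fell by 4.78 ± 0.24. GPR176 fell by 4.74 ± 0.34 and NTS, the neurotensin precursor, fell by 4.68 ± 0.64. Further probe sets gave -7.36 for MACC1-OT1, -3.57 and -4.13 for THY1 and -3.14 for GPR176. The probe set annotated to POU5F1B fell by 4.86 ± 0.21, but its sequence is shared with POU5F1 and it cannot be assigned to either gene. Altogether 3116 genes were called, of which 1113 rose and 907 fell at least 2-fold, and 495 called genes were present on both arrays of 1 day and neither of the other. Of 1576 called genes with several probe sets, 18 had 1 that moved over 2-fold the other way. The 3'/5' signal ratio of ACTB, a measure of RNA integrity, was higher at day 10 than at day 0. On the A chip it was 1.67 ± 0.31 (SD, n = 2) against 1.29 ± 0.019, and on the B chip 1.79 ± 0.28 against 1.42 ± 0.15. The ratio of GAPDH was 0.805 against 0.840 and 0.983 against 0.985. With the ACTB ratio as a covariate, chosen after the data were seen, 841 genes were higher and 875 lower, 1716 in all, and MIR99AHG had 4.17 ± 1.73 (adjusted p = 0.119). The count was 1852 without H1 day 0 replicate 2. MIR99AHG had a change of 3.07 without H1 day 0 replicate 1 and of 4.57 without H1 day 10 replicate 1, and was not called in either fit.

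**Figure D3:**
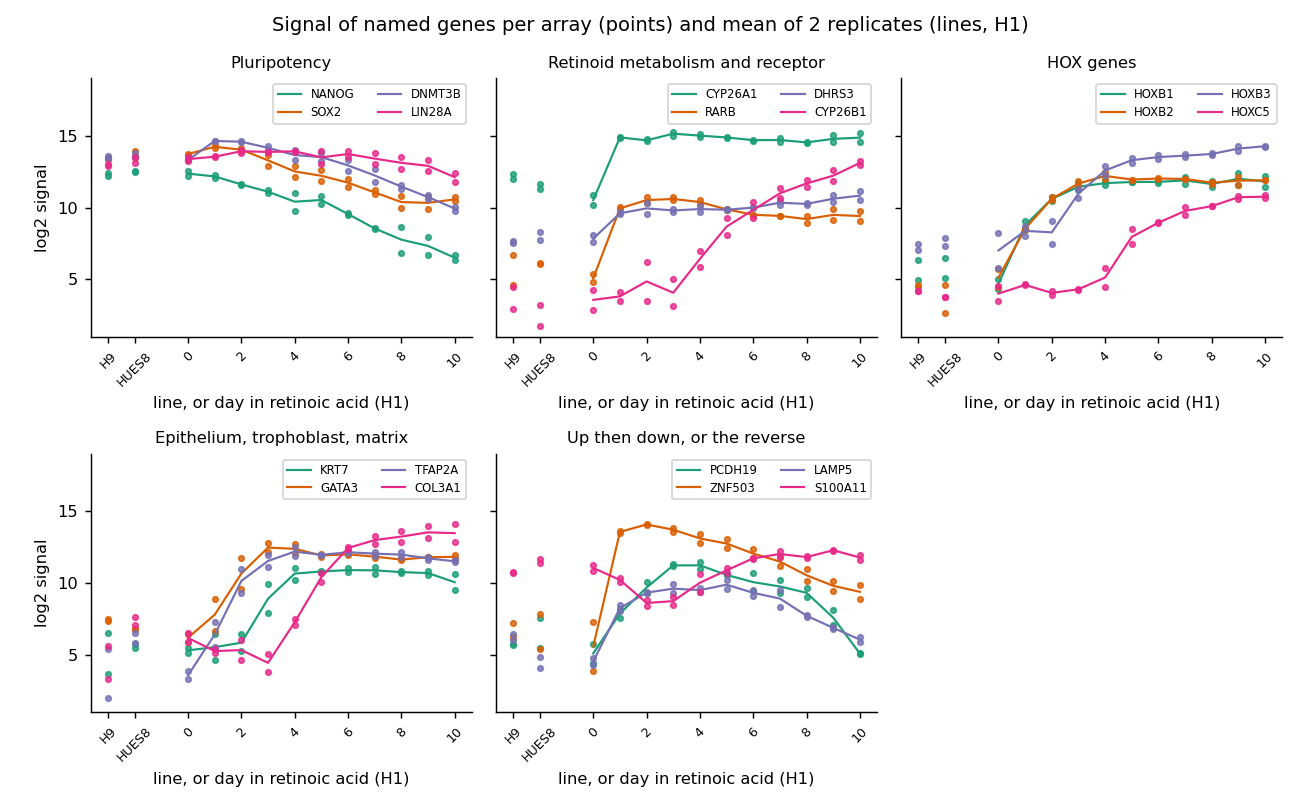
Log2 signal (vertical axis) of 20 named genes in H9 and HUES8 and in H1 by day in retinoic acid (horizontal axis), with points for each sample and lines for the H1 means of 2 replicates. CYP26A1 is up by 4.37 at day 1, NANOG falls through the course, and PCDH19, ZNF503 and LAMP5 peak before day 10.

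At day 10, 14 of the 26 lists passed. In the core pluripotency list 22 of 25 measured genes fell and none rose, also when adjusted over the list alone (adjusted p = 6.37e-22, and 0.00522 with an estimated correlation). GAL, the galanin precursor, was at least 70.1-fold lower and PRDM14, a repressor that guards pluripotency, at least 21.7-fold. DNMT3B fell by 3.39 ± 0.28, after its rise at day 1. LIN28A, an RNA-binding protein, fell by 1.26 ± 0.32 (adjusted p = 0.00615). LIN28A had adjusted p = 0.0626 without H1 day 0 replicate 2 and 0.0909 without H1 day 10 replicate 1. In the retinoid list 12 of 20 rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 1.74e-07, and 0.00541 with an estimated correlation). MEIS1 was at least 51.8-fold higher and RARB at least 15.8-fold, CYP26A1 was higher by 4.35 ± 0.22 and DHRS3 by 3.00 ± 0.27. LRAT, which stores retinol as an ester, and ALDH1A3, which makes retinoic acid, fell. Of HOX paralogs 1 to 5, 9 of 10 rose and none fell, also adjusted over the list alone (adjusted p = 1.79e-11, and 0.00272 with an estimated correlation). HOXC5 was at least 48.2-fold higher and HOXB1 at least 46.2-fold. Of HOX paralogs 6 to 13, 3 of 8 rose and none fell, also adjusted over the list alone (adjusted p = 0.00646, and 0.0313 with an estimated correlation). These were HOXB8, at least 35.7-fold higher, HOXB6, at least 30.1-fold, and HOXC6, at least 4.04-fold. Other probe sets gave 0.72 for HOXB6, 3.85 for HOXB8, 3.59 for HOXB1, -2.53 for GAL and 2.50 and 0.23 for RARB. Without H1 day 10 replicate 1 this list had adjusted p = 0.0515 and HOXC6 0.149, and without H1 day 0 replicate 1 HOXC6 had 0.180. These changes came with the ACTB ratios of 1.67 and 1.79 given above, and with that ratio as a covariate LIN28A had -0.99 ± 0.44 (adjusted p = 0.151). The fitted change of HOXC6 went from 2.81 ± 0.81 to 1.42 ± 1.05 (adjusted p = 0.429), and the median of HOX paralogs 6 to 13 from 1.01 to 0.47.

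Neural progenitor genes went both ways and more neuron genes fell than rose, while most genes called in the epithelial, crest and trophoblast lists were higher. Of 12 neural progenitor genes 3 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.592). DACH1 was at least 21.3-fold higher and ZIC1 at least 5.46-fold, though its second probe set gave -0.36 and with no detection filter its change was 0.21 (adjusted p = 0.905). OTX2, a forebrain factor, was at least 33.6-fold lower. In the neuron list 1 of 12 rose and 6 fell, 7 adjusted over the list alone (adjusted p = 0.00413, and 0.0313 with an estimated correlation). ISL1, a LIM homeobox factor, was at least 17.2-fold higher, TUBB3, a tubulin, fell by 2.78 ± 0.20 and NEFL, a neurofilament, fell by 1.99 ± 0.51. GAP43 was called lower but had no present call at day 0 or day 10. In the neural crest list 6 of 11 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.00176, and 0.0313 with an estimated correlation). TFAP2A was at least 82.4-fold higher, with other probe sets at 2.96 and 2.17, MSX2 at least 29.8-fold, TFAP2B at least 22.2-fold and MSX1 at least 21.3-fold. In the surface ectoderm list 4 of 7 rose, 5 adjusted over the list alone, and 1 fell (adjusted p = 0.00646, but adjusted p = 0.0845 with an estimated correlation). Besides TFAP2A these were DSC3, a desmocollin, at least 6.15-fold higher, PERP with 1.39 ± 0.25 and TFAP2C with 0.99 ± 0.22. In simple epithelium 12 of 16 rose and 1 fell, also adjusted over the list alone (adjusted p = 3.32e-08, and 0.0103 with an estimated correlation). KRT7, a keratin, was at least 26.8-fold higher and CLDN4, a tight junction claudin, at least 8.08-fold. KRT19 rose by 3.06 ± 0.23, DSP, a desmosomal plakin, by 2.92 ± 0.41 and KRT18 by 1.96 ± 0.20. Of 7 trophoblast genes measured from a list of 18, 5 rose and none fell, also adjusted over the list alone (adjusted p = 0.000133, and 0.0119 with an estimated correlation). Members not measured, such as CGA, are left out of that share. GATA3 was at least 49.7-fold higher, MUC15 at least 13.9-fold, VGLL1 at least 10.8-fold and GATA2 at least 5.57-fold. Other probe sets gave 7.02 and -0.42 for VGLL1, 0.56 for GATA2, 3.24 and 3.79 for DACH1, -3.23 for OTX2, 4.21 for MSX2, 3.32 for TFAP2B and 2.68 and 5.97 for GATA3. NEFL had adjusted p = 0.106 without H1 day 0 replicate 2 and 0.137 without H1 day 10 replicate 1, and DSC3 0.121 and 0.0835. These changes too came with the ACTB ratios of 1.67 and 1.79, and with the covariate NEFL had -1.58 ± 0.71 (adjusted p = 0.156). Fitted changes went from 5.60 ± 1.09 to 4.09 ± 1.45 for TFAP2B (adjusted p = 0.0681), from 2.62 ± 0.68 to 1.94 ± 0.93 for DSC3 (0.184) and from 3.26 ± 0.61 to 2.40 ± 0.81 for GATA2 (0.0563). The median of the neural progenitor list went from -0.97 to -0.57 and that of the trophoblast list from 3.26 to 2.4, while neural crest went from 2.21 to 2.29.

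Endoderm and mesoderm markers were split. Of 11 definitive endoderm genes 3 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.654). Beside GATA6, the pioneer factors FOXA1 and FOXA2 were at least 12.7-fold and 8.98-fold higher, and CER1, a Nodal antagonist, was at least 6.38-fold lower. With no detection filter a different probe set stood for FOXA2 and gave -0.34. Of 6 hepatic and visceral endoderm genes 2 rose, also adjusted over the list alone (adjusted p = 0.0711). These were APOA2, an apolipoprotein, at least 11.5-fold higher and TTR, transthyretin, at least 10.9-fold. Of 4 primitive streak genes PDGFRA rose, at least 9.19-fold, and EOMES was at least 4.81-fold lower, with 1 up and 2 down adjusted over the list alone (adjusted p = 0.721). Neither cardiac gene measured was called, also adjusted over the list alone (adjusted p = 0.654), with ACTC1 at -0.59 ± 0.27 and MYL4 at 0.03 ± 0.35. In the smooth muscle, fibroblast and matrix list 7 of 25 rose and 7 fell, 8 and 8 adjusted over the list alone (adjusted p = 0.807). Those that rose were collagens and other matrix genes such as COL3A1 and COL1A1, with 3.45 ± 0.30, and the contractile gene TAGLN fell by 2.28 ± 0.38. Other probe sets gave 1.56 and 1.02 for COL1A1 and -0.19 for TAGLN. Of 6 endothelial genes KDR, a VEGF receptor, was at least 17.7-fold lower and no other was called, also adjusted over the list alone (adjusted p = 0.351). Of 2 blood genes HBE1, an embryonic globin, was at least 6.31-fold higher, also adjusted over the list alone (adjusted p = 0.654). HBE1 had adjusted p = 0.150 without H1 day 0 replicate 1 and 0.128 without H1 day 10 replicate 2. The day 10 arrays here had the ACTB ratios of 1.67 and 1.79, and with the covariate the fitted change of HBE1 went from 2.96 ± 0.87 to 2.79 ± 1.23 (adjusted p = 0.147). List medians went from 0.65 to 0.27 for definitive endoderm and from 1.79 to 0.78 for hepatic and visceral endoderm. They grew in size from -0.89 to -1.39 for primitive streak and from 1.16 to 1.58 for blood.

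Of the genes called in the cell division and glycolysis lists at day 10, all but 1 were lower. In the mitosis list 14 of 23 fell and none rose, also adjusted over the list alone (adjusted p = 1.74e-07, and 0.00541 with an estimated correlation). PLK1, a mitotic kinase, fell by 1.44 ± 0.30, CDK1 fell by 1.23 ± 0.25, AURKB fell by 1.21 ± 0.18 and BUB1, a checkpoint kinase, fell by 1.19 ± 0.24. In the DNA replication list 13 of 21 fell, 15 adjusted over the list alone, and none rose (adjusted p = 7.73e-07, but adjusted p = 0.0852 with an estimated correlation). MCM5, a helicase subunit, fell by 1.70 ± 0.23, RRM2 fell by 1.36 ± 0.24, CDT1 fell by 1.19 ± 0.29 and CDC6 fell by 1.15 ± 0.28. In glycolysis 12 of 20 fell and 1 rose, also adjusted over the list alone (adjusted p = 4.07e-05, but adjusted p = 0.115 with an estimated correlation). HK1, a hexokinase, fell by 1.73 ± 0.19, PGAM1 fell by 1.38 ± 0.22, PKM fell by 1.33 ± 0.19 and ALDOC fell by 1.30 ± 0.24. Other probe sets gave -0.04 for PKM, -3.41 for MCM5 and -1.62, -0.36 and -0.48 for BUB1, and with the mean of its probe sets BUB1 had adjusted p = 0.0881. Of 13 cholesterol synthesis genes 5 fell, 6 adjusted over the list alone, and none rose (adjusted p = 0.0711). FDPS fell by 1.11 ± 0.36, HMGCS1 fell by 0.69 ± 0.23, LSS fell by 0.69 ± 0.24, and EBP fell by 0.60 ± 0.20. The cholesterol list had adjusted p = 0.0357 without H1 day 0 replicate 1, 0.0427 without H1 day 10 replicate 1 and 0.0331 after centring on control probe sets. With the mean of probe sets adjusted p was 0.356 for LSS, 0.0749 for EBP and 0.0511 for HMGCS1. With only the groups compared it was 0.0975 for LSS, 0.0744 for EBP and 0.0508 for CDT1, and with only the H1 arrays 0.0574 for LSS and 0.0501 for HMGCS1. It was 0.0505 for LSS with no detection filter and 0.0570 for FDPS with no intensity trend. Adjusted p without H1 day 0 replicate 2 was 0.138 for FDPS, 0.286 for HMGCS1, 0.164 for LSS, 0.107 for EBP and 0.0831 for CDC6. Without H1 day 10 replicate 2 it was 0.136 for FDPS, 0.125 for HMGCS1, 0.339 for LSS, 0.270 for EBP and 0.110 for CDT1. For H1 day 0 replicate 1 left out it was 0.0845 for FDPS, 0.104 for LSS, 0.108 for EBP and 0.104 for CDT1, and without H1 day 10 replicate 1 it was 0.0759 for FDPS and 0.101 for HMGCS1. The day 10 ACTB ratios were 1.67 and 1.79, and with the covariate changes were -0.83 ± 0.50 for FDPS (adjusted p = 0.313), -0.67 ± 0.33 for HMGCS1 (0.204), -0.76 ± 0.34 for LSS (0.150), -0.58 ± 0.28 for EBP (0.186), -0.80 ± 0.37 for CDC6 (0.173) and -0.98 ± 0.33 for ALDOC (0.0528). The median of the glycolysis list went from -0.74 to -0.45.

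The BMP and WNT targets called at day 10 were all higher, while p53, interferon and stress genes went both ways. In the BMP list 6 of 11 rose, 7 adjusted over the list alone, and none fell (adjusted p = 5.97e-05, but adjusted p = 0.0845 with an estimated correlation). BMP4 itself was at least 16.8-fold higher, ID2 rose by 2.81 ± 0.37, ID3 by 1.89 ± 0.35 and BAMBI, a decoy receptor, by 1.55 ± 0.48. Of 7 WNT targets 3 rose and none fell, also adjusted over the list alone (adjusted p = 0.0203, but adjusted p = 0.116 with an estimated correlation). TNFRSF19 was at least 17.1-fold higher, LEF1, a nuclear mediator of WNT signals, at least 11.2-fold and RNF43 at least 4.15-fold. For TNFRSF19 other probe sets gave 2.49 and 2.53, and for LEF1 2.13. Of 13 p53 targets 3 rose, 4 adjusted over the list alone, and 2 fell (adjusted p = 0.904), and median and test differed in sign. TP53INP1 rose by 2.57 ± 0.24 and GDF15 by 1.18 ± 0.39, while RRM2B fell by 1.83 ± 0.29 and BAX, a proapoptotic protein, fell by 1.18 ± 0.21. With no detection filter a different probe set stood for GDF15 and gave -0.50, and with control centring its adjusted p was 0.0555. Of 21 interferon and MHC class I genes 3 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.916). TAP1, a peptide transporter, was at least 2.78-fold higher and IRF9 rose by 1.33 ± 0.26, while IFITM1 fell by 2.47 ± 0.32 and ISG15 fell by 1.70 ± 0.26. Of 13 stress genes 3 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.302). HERPUD1, of endoplasmic reticulum degradation, rose by 2.44 ± 0.22, DNAJB9 by 1.54 ± 0.20 and DNAJB1 by 1.23 ± 0.15, and CHAC1 was at least 3.02-fold lower. The WNT list had adjusted p = 0.0504 without H1 day 0 replicate 1, 0.133 without H1 day 10 replicate 1 and 0.122 with the ACTB ratio, 1.67 and 1.79 at day 10, as a covariate. That covariate gave changes of 1.18 ± 0.43 for ID3 (adjusted p = 0.0744), 0.98 ± 0.65 for BAMBI (0.364), 1.33 ± 0.55 for GDF15 (0.118) and 0.97 ± 0.35 for IRF9 (0.0744). Fitted changes went from 3.48 ± 0.87 to 2.98 ± 1.22 for LEF1 (adjusted p = 0.117), from 2.05 ± 0.49 to 1.84 ± 0.69 for RNF43 (0.0876), from 1.48 ± 0.32 to 1.26 ± 0.44 for TAP1 (0.0655) and from -1.59 ± 0.44 to -1.73 ± 0.62 for CHAC1 (0.0703). List medians went from 1.14 to 0.68 for BMP targets and from 0.74 to 0.24 for WNT targets. That of the interferon list grew from 0.31 to 0.48, and that of p53 targets turned from -0.09 to 0.06. Adjusted p without H1 day 0 replicate 2 was 0.121 for BAMBI, 0.268 for GDF15, 0.0541 for LEF1, 0.0751 for RNF43 and 0.173 for CHAC1. Without H1 day 10 replicate 1 it was 0.394 for BAMBI, whose change was then 0.65, 0.0611 for GDF15 and 0.0683 for LEF1. Without H1 day 10 replicate 2 it was 0.165 for GDF15 and 0.143 for CHAC1, and without H1 day 0 replicate 1 it was 0.0660 for BAMBI.

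**Figure D4:**
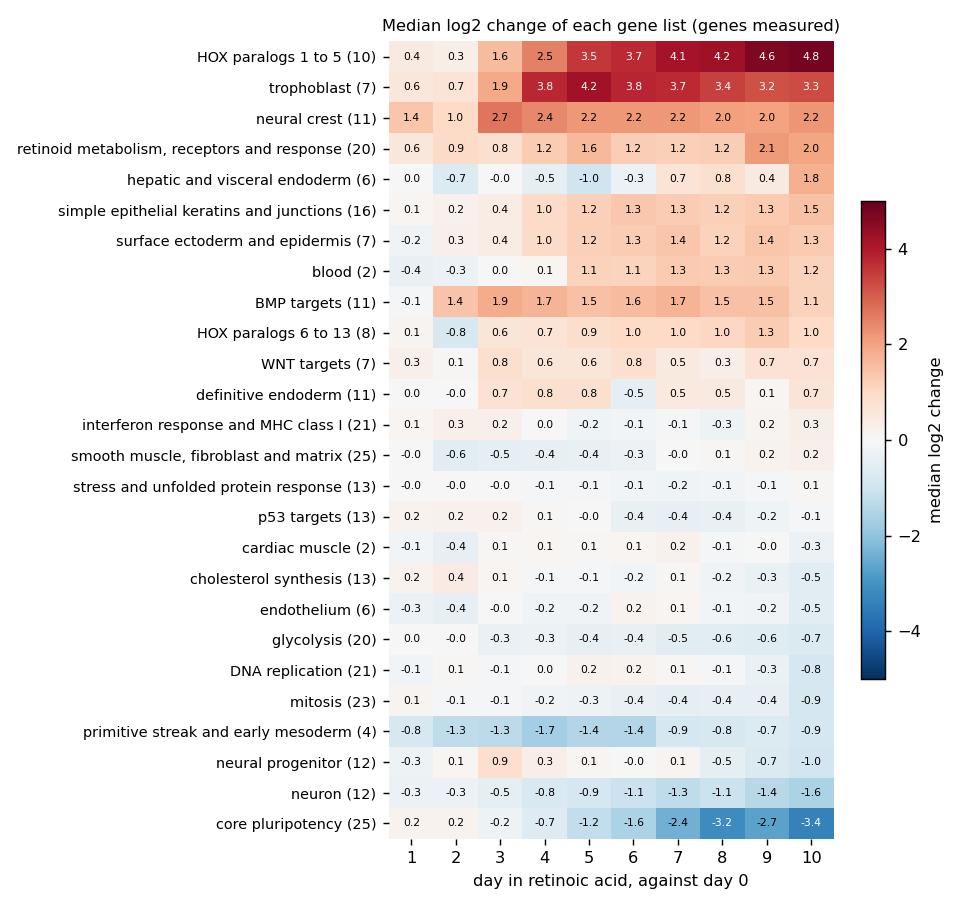
Median log2 change against day 0 (colour and printed value) of the measured genes in each of the 26 lists (vertical axis, number of genes in brackets) by day in retinoic acid (horizontal axis). Members absent at day 0 enter with their fitted change, which is not a bound. HOX paralogs 1 to 5 reach a median of 4.80 and core pluripotency -3.36 at day 10, or 4.06 and -3.34 with such members at their bounds.

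Comparing day 10 with each of the 3 undifferentiated lines asked which changes held in the same direction against every line. Most changes of pluripotency genes and of HOX paralogs 1 to 5 did so. The size of a change was not compared with that of the differences between lines. NANOG and SOX2 were lower than in every line, and 21 of 25 core pluripotency genes were, with none higher. Of HOX paralogs 1 to 5, 9 of 10 were higher than in every line, against 2 of 8 of paralogs 6 to 13. Also higher than in every line were 10 of 20 retinoid genes, 10 of 16 simple epithelial genes and 5 of 7 trophoblast genes. In glycolysis 11 of 20 genes were lower than in every line, in DNA replication 10 of 21 and in mitosis 5 of 23. Of the neural crest genes 6 were higher and 2 lower. In all, 882 genes were higher and 925 lower. The count of 1807 was 1163 without H1 day 0 replicate 2 and 1150 without H1 day 10 replicate 2, and 374 were higher and 406 lower with the ACTB covariate, added after the data were seen.

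A small class of genes rose early and fell again by day 10. PCDH19, a protocadherin, was at least 31.2-fold higher at day 3 than at day 0 and at least 45.4-fold higher than at day 10 (adjusted p = 9.95e-06). LAMP5, a lysosomal membrane protein, was at least 21.9-fold and 11.7-fold higher (adjusted p = 5.65e-05). ZNF503 was at least 120-fold higher than at day 0 and fell by 4.33 from day 3 to day 10 (adjusted p = 0.00786), and C11orf96 was at least 10.6-fold and 20.4-fold higher (adjusted p = 0.0140). HTR1D, a serotonin receptor, was called (adjusted p = 0.0451) but had no present call on these days. The class held 37 genes and the reverse class 3. S100A11, a calcium-binding protein, fell by 2.31 ± 0.30 by day 3 and then rose by 3.04 (adjusted p = 0.00301). AMOTL1 was at least 3.20-fold lower at day 3 than at day 0 and at least 3.78-fold lower than at day 10 (adjusted p = 0.00567). FAT3, an atypical cadherin, was at least 4.21-fold and 5.87-fold lower (adjusted p = 0.0449). The 37 became 12 without H1 day 0 replicate 1, 13 without H1 day 0 replicate 2, 13 without H1 day 3 replicate 1 and 8 without H1 day 3 replicate 2. In the same order the 3 became 1, 0, 24 and 3, and 5 without H1 day 10 replicate 2. Without H1 day 3 replicate 2 adjusted p was 0.204 for ZNF503, 0.262 for C11orf96, 0.711 for HTR1D, 0.0567 for S100A11, 0.0818 for AMOTL1 and 0.343 for FAT3. Without H1 day 3 replicate 1 it was 0.0817 for ZNF503, 0.132 for C11orf96 and 0.231 for HTR1D. With H1 day 0 replicate 1 left out it was 0.406 for C11orf96, 0.616 for HTR1D, 0.236 for AMOTL1 and 0.746 for FAT3. With H1 day 0 replicate 2 left out it was 0.0923 for HTR1D, 0.131 for S100A11, 0.131 for AMOTL1 and 0.298 for FAT3. Without H1 day 10 replicate 2 it was 0.127 for ZNF503, 0.0657 for HTR1D and 0.0889 for FAT3, and without H1 day 10 replicate 1 it was 0.0615 for HTR1D. With the mean of its probe sets AMOTL1 had adjusted p = 1. With no detection filter adjusted p was 0.0590 for HTR1D and 0.0570 for FAT3, after control centring 0.0946 and 0.117, and with only the H1 arrays FAT3 had 0.0698. With no intensity trend adjusted p was 0.0584 for C11orf96, 0.0743 for ZNF503 and HTR1D, and 0.171 for FAT3. With only the groups compared it was 0.291 for C11orf96, 0.0745 for ZNF503, 0.380 for HTR1D and 0.104 for AMOTL1, and with the ACTB covariate 0.121 for HTR1D and 0.0521 for FAT3. Centring on control probe sets gave 16 and 6 genes, no intensity trend gave 11 for the larger class, and the replicate block gave 15 for the smaller.

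Comparing each day with the day before asked where the steps lie, and calls were few after day 3. From day 1 to day 2, 31 genes rose and 13 fell, and from day 2 to day 3, 11 rose and 0 fell. From day 3 to day 4, 3 rose: PLXNA2, a semaphorin receptor absent at day 3, at least 5.69-fold, IGFBP3 by 1.78 ± 0.27 and HERPUD1 by 1.30 ± 0.22. From day 4 to day 5 HOXC5 was called higher (adjusted p = 0.0366) but had no present call on these days. From day 7 to day 8 SELENOM, a selenoprotein present on 1 of 2 arrays at day 7, fell to absent, at least 4.71-fold (adjusted p = 0.0338). These 5 genes were named after their values were seen. The steps into days 6, 7, 9 and 10 had 0 genes in limma, with 358, 314, 511 and 563 genes at an unadjusted p under 0.05. Each of these is less than a share of 0.05 of the 12183 genes tested, the share expected without any change. Without H1 day 2 replicate 1 the first step had 10 genes, and without H1 day 1 replicate 2 it had 23. The step into day 3, with only rises above, had 51 rises and 1 fall, 3 rises, 1 rise and 26 falls, and 14 rises and 3 falls without H1 day 2 replicate 1, H1 day 2 replicate 2, H1 day 3 replicate 1 and H1 day 3 replicate 2. The step into day 4 had 56 without H1 day 3 replicate 1, 1 without H1 day 3 replicate 2 and 16 without H1 day 4 replicate 2. Leaving out any 1 replicate of the days compared gave 2 to 7 genes for day 5, 1 to 4 for day 6, 1 to 5 for day 7, 0 to 7 for day 8, 3 to 7 for day 9 and 4 to 19 for day 10. Quantile normalization gave 28 higher and 5 lower for the first step.

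The undifferentiated lines were compared to measure differences between stem cell lines. EDNRB, the endothelin B receptor, was far higher in H9 and HUES8 than in untreated H1 cells, by 4.35 ± 0.40 (adjusted p = 1.78e-06) and 4.10 ± 0.40 (adjusted p = 1.30e-05). H9 differed from H1 in 544 genes and HUES8 in 24. In H9, SHISA9 was higher than in H1 by 3.46 ± 0.33, NBPF3 by 2.53 ± 0.35 and SMIM3 by 2.45 ± 0.31. GABPB1-AS1 had a change of -3.18 ± 0.29, EGR1, an immediate early factor, -3.13 ± 0.61, CYBRD1, an iron reductase, -3.12 ± 0.87, and PTCH1, the hedgehog receptor, -2.35 ± 0.52. In HUES8, FAT3 was higher than in H1 by 1.78 ± 0.36, ACTC1, cardiac actin, by 1.62 ± 0.27 and CD81, a tetraspanin, by 1.54 ± 0.30. MIX23 had a change of -2.53 ± 0.28, PSPH, of serine synthesis, -2.42 ± 0.28, HLA-DPB2 -2.18 ± 0.43 and SLC60A2 -1.95 ± 0.38. With the mean of all probe sets PSPH had -0.89 (adjusted p = 0.371) and SLC60A2 -1.02 (adjusted p = 0.238). With only the groups compared adjusted p was 0.179 for CD81 and 0.133 for SLC60A2, and with control centring it was 0.341 for FAT3, 0.106 for CD81 and 0.106 for SLC60A2. HUES8 exceeded H9 in EGR1 by 2.74 ± 0.61, ZNF667 by 2.72 ± 0.35, PTCH1 by 2.47 ± 0.52 and RIMS2 by 2.46 ± 0.43. IER3 had a change of -2.46 ± 0.35, TSC22D3 -2.29 ± 0.30, HLA-C -2.16 ± 0.15 and SMIM3 -2.15 ± 0.31. HLA genes vary between people, so a probe set can bind their alleles unequally. The splits were 258 higher and 286 lower for H9 against H1, 10 and 14 for HUES8 against H1, and for HUES8 against H9 190 of 308 were higher. After centring on control probe sets the median change of all genes was -0.23, -0.11 and 0.12 in these comparisons and the splits were 86 and 457, 4 and 11, and 194 and 63, and quantile normalization gave 12 and 11 for HUES8 against H1. The count of H9 against H1 rose to 1583 with only the groups compared and to 1020 with the replicate number as a block, and was 343 with a 2-fold minimum. The block gave 49 for HUES8 against H1 and 525 for HUES8 against H9, and no intensity trend gave 14 for HUES8 against H1. The 544 of H9 against H1 became 85 higher and 68 lower without H1 day 0 replicate 1, 187 genes without H1 day 0 replicate 2, 190 without H9 replicate 1 and 235 without H9 replicate 2. HUES8 against H9 gave 84 higher and 33 lower without H9 replicate 1, and counts of 203 without H9 replicate 2, 159 without HUES8 replicate 1 and 120 without HUES8 replicate 2. A floor on low signals left CYBRD1 at -1.53 (adjusted p = 0.102), and its adjusted p was 0.0676 with no detection filter, 0.0763 with no intensity trend and 0.0516 with only the groups compared. No intensity trend gave adjusted p of 0.106 for FAT3, 0.106 for CD81, 0.129 for HLA-DPB2, 0.0885 for SLC60A2 and 0.0539 for EGR1 against HUES8, and no detection filter gave 0.0575 for FAT3. Leaving out 1 replicate at a time took CYBRD1, EGR1, PTCH1, FAT3, ACTC1, CD81, HLA-DPB2, SLC60A2 and RIMS2 past the threshold, with -1.18 (adjusted p = 0.545) for CYBRD1 without H9 replicate 2. Without H1 day 0 replicate 1 adjusted p was 0.238 for CYBRD1, 0.108 for PTCH1, 0.132 for FAT3, 0.104 for ACTC1, 0.159 for HLA-DPB2 and 0.202 for SLC60A2. Without H1 day 0 replicate 2 it was 0.115 for CYBRD1, 0.0604 for PTCH1, 0.217 for FAT3, 0.286 for CD81, whose change was then 0.85, 0.153 for HLA-DPB2 and 0.101 for SLC60A2. Without HUES8 replicate 1 it was 0.447 for FAT3, 0.129 for ACTC1, 0.220 for CD81 and 0.0566 for HLA-DPB2. Without HUES8 replicate 2 it was 0.117 for CD81, 0.272 for HLA-DPB2 and 0.284 for SLC60A2, and against H9 0.225 for EGR1 and 0.149 for PTCH1. Without H9 replicate 1 it was 0.0620 for EGR1 and 0.0945 for PTCH1 against H1, and 0.153 and 0.1 against HUES8. Without H9 replicate 2 it was 0.0653 for PTCH1 against H1, and 0.0534 for EGR1, 0.0584 for PTCH1 and 0.0602 for RIMS2 against HUES8.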

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

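The covariate of the ACTB ratio was chosen only after the results were seen, and the other alternatives were planned. Reading the series table instead of the matrix changed no result. Of 165 results for named genes, all kept their call under quantile normalization, the replicate block and the series table, as did all 163 that remained under the stricter filter. Calls were lost for 6 under control centring, 9 with no detection filter, 1 with a floor, 12 with no intensity trend, 8 with the mean of probe sets, 3 with only the H1 arrays, 10 with only the groups compared, 4 with a 2-fold minimum and 24 with the ACTB covariate. Of the 9 with no detection filter, FOXA2 reversed to -0.34 and GDF15 to -0.5 at day 10, because another probe set then stood for the gene. The cause of the other changes was not tested, except that leaving out arrays leaves fewer samples.

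Quantile normalization gave 6 genes for day 3 against day 2, 0 for day 8 against day 7 and 1 for day 10 against day 9. Control probe set centring gave 90 for day 1 against day 0, 18 for day 2 against day 1, 3 for day 3 against day 2, 0 for day 5 against day 4, 15 for HUES8 against H1, 16 for a rise then fall and 6 for a fall then rise. After it the median change of all genes was 0.10 at day 10 against day 0 and 0.17 at day 10 against day 9. No detection filter gave 27 for day 2 against day 1, 1 for day 4 against day 3, 0 for day 5 against day 4 and 0 for day 8 against day 7. The stricter detection filter gave 6 for day 4 against day 3, and the floor gave 13 for that step and 3 for day 5 against day 4. No intensity trend gave 24 for day 2 against day 1, 0 for day 3 against day 2, 0 for day 4 against day 3, 0 for day 8 against day 7, 14 for HUES8 against H1 and 11 for a rise then fall. The mean of all probe sets gave 7 for day 3 against day 2, 7 for day 4 against day 3 and 2 for day 5 against day 4. Only the H1 arrays gave 6 for day 4 against day 3 and 2 for day 5 against day 4. Only the arrays of the groups compared gave 86 for day 1 against day 0, 2 for day 2 against day 1, 4 for day 3 against day 2, 0 for day 4 against day 3, 0 for day 8 against day 7 and 1583 for H9 against H1. The 2-fold minimum gave 2020 for day 10 against day 0 and 343 for H9 against H1. With the ACTB covariate the counts were 1716 for day 10 against day 0, 13 for day 4 against day 3 and 780 for day 10 against each of 3 lines. Where limma gave 0 genes, the genes at an unadjusted p under 0.05 in the same fit were 641 for day 8 against day 7 with quantile normalization and 282 for day 5 against day 4 with control centring. With no detection filter they were 693 for day 5 against day 4 and 819 for day 8 against day 7. With no intensity trend they were 694 for day 3 against day 2, 731 for day 4 against day 3 and 578 for day 8 against day 7. With only the groups compared they were 581 for day 4 against day 3 and 537 for day 8 against day 7. Without any change a share of 0.05 of the genes tested is expected, of 12183 genes or of 17486 with no detection filter. The counts of 641, 694 and 731 lay above that share and the others below it.

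The replicate number as a replicate block gave 253 for day 1 and 727 for day 2 against day 0, 24 for day 3 against day 2, 15 for day 4 against day 3, 2 for day 10 against day 9, 1020 for H9 against H1, 49 for HUES8 against H1, 525 for HUES8 against H9 and 15 for a fall then rise. With the block the primitive streak list had adjusted p = 0.083 at day 1. Deviations of same-numbered samples from their group means correlated with r from -0.05 to 0.31 over the 55 pairs of H1 days (median 0.1, 26 over 0.1) and from -0.07 to 0.31 over all 78 pairs. On principal component 1 replicate 1 lay above replicate 2 on each of the 11 H1 days, by the most at day 4 (17.0 against -6.26). The labels do not say that a number marks a shared culture or day, so the samples were treated as sharing only a number.

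Of the gene lists, 2 of 4 passed at day 1 with only the groups compared and 1 with an estimated correlation, and 9 of 14 passed at day 10 with an estimated correlation. At day 1 the primitive streak list had adjusted p = 0.07 under control centring, 0.134 with no detection filter, 0.0919 with the stricter filter, 0.0598 with only the H1 arrays and 0.192 with an estimated correlation. HOX paralogs 1 to 5 had 0.184 with only the groups compared and 0.233 with an estimated correlation, and neural crest had 0.0902 with a floor, 0.103 with only the groups compared and 0.0667 with an estimated correlation. DNA replication at day 1 passed under control centring (0.0178). At day 10 an estimated correlation gave 0.0845 for surface ectoderm and for BMP targets, 0.0852 for DNA replication, 0.116 for WNT targets and 0.115 for glycolysis. WNT targets had 0.0611 with no detection filter, 0.0618 with the mean of probe sets and 0.122 with the ACTB covariate. Hepatic endoderm passed with no detection filter (0.0417), a floor (0.00837), only the groups compared (0.0301) and fry (0.000444). Cholesterol synthesis passed under control centring (0.0331), no detection filter (0.0417), only the groups compared (0.0488) and fry (0.0374). With fry, endothelium (0.00076) and stress (0.012) passed as well.

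Leaving out each replicate in turn leaves 1 sample in a group, which is then assumed to vary like the other groups. The lowest and highest counts were 88 and 150 for day 1 against day 0, 244 and 273 for day 2, 361 and 401 for day 3, 547 and 659 for day 4, 747 and 1007 for day 5, 940 and 1159 for day 6, 1190 and 1454 for day 7, 1202 and 1314 for day 8, 1523 and 1796 for day 9 and 1852 and 2354 for day 10. They were 10 and 47 for day 2 against day 1, 3 and 52 for day 3 against day 2, 1 and 56 for day 4 against day 3, 2 and 7 for day 5 against day 4, 1 and 4 for day 6 against day 5, 1 and 5 for day 7 against day 6, 0 (1189 in limma at an unadjusted p under 0.05, without H1 day 7 replicate 1) and 7 for day 8 against day 7, 3 and 7 for day 9 against day 8 and 4 and 19 for day 10 against day 9. They were 153 and 235 for H9 against H1, 17 and 35 for HUES8 against H1, 117 and 203 for HUES8 against H9, 1150 and 1422 for day 10 against each of 3 lines, 8 and 27 for a rise then fall, 0 and 24 for a fall then rise, and 2872 and 3486 for the F test. The libraries that moved a count by over 1.5 times are named with the counts in the report. Adjusted p of lists whose call changed ranged from 0.00542 to 0.11 for HOX paralogs 1 to 5, 0.0327 to 0.211 for primitive streak and 0.0375 to 0.589 for BMP targets at day 1. At day 10 the ranges were 0.000949 to 0.0515 for HOX paralogs 6 to 13, 0.00241 to 0.133 for WNT targets and 0.0357 to 0.249 for cholesterol synthesis. Of the 165 named gene results, 130 kept their call whichever replicate was left out and 35 lost it at least once. Signal over background limits genes called absent in a group, whose change is known only as a bound.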

Other observations

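The tests between lines, of the stress genes of H9, of the scaling of H9, of the H9 genes along the course, of the ACTB covariate and of the onset of HOX genes, with and without those never called, were chosen only after the results were seen. The gene lists were also tested between the undifferentiated lines. In HUES8 the neural crest list was higher than in H1 (adjusted p = 2.94e-08, and 0.00407 with an estimated correlation), with EDNRB and DLX5 called. The smooth muscle, fibroblast and matrix list was higher too (adjusted p = 2.24e-05, and 0.0403 with an estimated correlation). In H9 the p53 list (2.60e-05), the stress list (4.69e-05) and the matrix list (0.0118) were higher than in H1 and the mitosis list lower (0.00176). With an estimated correlation these adjusted p were 0.150, 0.150, 0.185 and 0.150. The p53 targets CDKN1A, SESN2 and TNFRSF10B were higher by 1.08, 1.19 and 0.88, and BUB1, CDK1, NUSAP1 and TTK were called lower. Between HUES8 and H9 the p53 (3.03e-05), stress (0.000141) and interferon (0.00320) lists were lower and the mitosis (0.000361) and neural progenitor (0.0134) lists higher in HUES8. Their adjusted p with an estimated correlation were 0.105, 0.192, 0.215, 0.105 and 0.215.

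H9 differed from H1 in 544 genes, and HUES8 in 24. Scaling of the arrays was looked at through the size of the H9 count under other scalings, which does not decide it. The count was 537 under quantile normalization and 543 under control centring. Centring turned the split from 258 higher and 286 lower to 86 and 457, and quantile normalization gave 262 and 275. The direction of the H9 changes, and so which genes were called, thus depended on the scaling. Under centring the total stayed close to 544 because calls lost in one direction were offset by calls gained in the other. Scaling thus stays open as a contribution to the H9 changes. The count was 153 to 235 with 1 replicate left out, 1020 with the replicate block and 1583 with only the groups compared. Differentiation of H9 along the retinoic acid course as the whole cause was looked at through the 544 genes, which does not decide it. The 544 genes changed by a median of 1.12 in H9 (1.07 to 1.17 over the 4 pairs of samples), and in the same direction by at most 0.34 on any day of the course (day 5, 0.22 to 0.44) and by 0.31 in HUES8. All share the day 0 samples by which the genes were called, which tends to raise these values. The genes were also called in these H9 samples, which raises the 1.12 but not the values of the course or of HUES8. A smaller change on the course was thus likely in advance. The values show only that these genes as a set moved less on the course than in H9. Differentiation of H9, whole or partial, stays open as a cause. The median of 25 core pluripotency genes in HUES8 minus H9 was -0.04, but in treated H1 cells it was 0.17 at day 1, 0.17 at day 2 and -0.24 at day 3, so a value near 0 does not exclude an early stage. CYP26A1, DLX5, BMP4 and ID1 were called higher in H9 than in H1, while DLX5 and BMP4 were called higher in HUES8 too and 1 of 20 retinoid genes was called in H9. A stress response in the H9 cultures stays open too. Their stress list was higher than in HUES8 (adjusted p = 0.000141, but 0.192 with an estimated correlation), a test that reuses the 2 H9 samples in which the stress genes were first seen to be higher. A difference between lines and one between the days on which they were handled stay open, because each line was sampled in 1 group.

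The ACTB 3'/5' ratio was higher at day 10 than at day 0, which may mean lower RNA integrity in the later samples. The rise was larger in day 10 replicate 1. Replicates 1 and 2 had 1.892 and 1.449 on the A chip at day 10, against 1.299 and 1.272 at day 0. On the B chip they had 1.984 and 1.589 against 1.532 and 1.314. The GAPDH ratio was not higher at day 10, with 0.805 against 0.840 on the A chip and 0.983 against 0.985 on the B chip. Lower integrity as the whole cause of the day 10 changes is argued against by the core pluripotency list, whose median change was -3.15 with the ratio as a covariate and -3.36 without it. Other list medians shrank by more. They went from 3.26 to 2.4 for trophoblast, from 4.8 to 4.52 for HOX paralogs 1 to 5 and from 1.01 to 0.47 for HOX paralogs 6 to 13. Hepatic endoderm went from 1.79 to 0.78, definitive endoderm from 0.65 to 0.27 and BMP targets from 1.14 to 0.68. WNT targets went from 0.74 to 0.24, glycolysis from -0.74 to -0.45 and neural progenitors from -0.97 to -0.57. The matrix list, from 0.25 to 0.13, shrank by less on this scale. The part of this shrinking that RNA integrity accounts for stays open. Some medians grew in size, from -0.89 to -1.39 for primitive streak, from 1.16 to 1.58 for blood and from 0.31 to 0.48 for interferon. That of p53 targets turned from -0.09 to 0.06. The count of genes fell from 3116 to 1716 with the covariate. The 1574 genes that lost their call had a median change of 1.02 in size with a median SE of 0.29 before, and 0.80 with 0.37 after. In 952 of them the change stayed within 1 SE of its earlier value, so their lost call alone does not point to RNA integrity. In 610 the change shrank by over 1 SE, and for these an effect of RNA integrity and one of differentiation stay open. The fit kept a mean per group, so its slope on the ratio came only from differences between replicates of a group. The day 10 pair differed the most, with an SD of 0.31 on the A chip and 0.28 on the B chip, and so weighed heavily on that slope. Of 22 named genes that lost their call at day 10, 13 stayed within 1 SE. No biological cause of the ratio was tested.

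More genes rose by day 3 and fell by day 10 than the reverse, 37 against 3. The ratio of the counts was 2.67 under control centring and 10 under quantile normalization. Without H1 day 3 replicate 1 the order reversed, with 13 genes against 24. Scaling of the arrays, single samples and a transient change over the course stay open as sources of this asymmetry, because control centring narrowed it without ending it, 1 sample reversed it and the smaller class holds few genes.

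HOX genes may be called in the order of their paralog groups, as a hypothesis from the early calls of HOXB1 and HOXB2. Both genes stay in the tests below, which thus partly reuse the calls that raised the hypothesis. Over 14 HOX genes called on at least 1 day, the paralog group and the first day called had a Spearman rho of 0.46 (p = 0.0959 from 1e+05 permutations across genes, which are not independent). Pearson r was 0.45 (p = 0.106), and 0.41 without the 2 genes farthest from the median paralog group. The test left the order open, with HOXD4 first called on day 9 and HOXB8 on day 4 among the exceptions. It left out HOXD8, HOXB9, HOXC10 and HOXD10, of paralog groups 8 to 10, which were never called and so go with the order. Placed after the last day, they gave rho 0.74 over 18 genes (p = 0.000630), but a gene not called by day 10 has no onset, so this value does not separate a later onset from none.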
